A study of Mus musculus with 8 samples.

How the data were processed

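The samples were hearts of mice heterozygous for Pcyt2, labelled as myocardium, from 4 males and 4 females. Per the labels' protocols, the mice were 8 months old, the hearts were collected 3 to 4 hours after lights on and frozen, and biotin-labelled RNA was made from 100 ng of total RNA for a short-oligonucleotide expression array. The labels call the samples biological replicates. All of them carry the same genotype, so sex is the comparison the design holds, and wild-type hearts were not analysed here.

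The deposited table holds values on a log2 scale for 34351 probe sets on 8 arrays. The log base and the software for background correction, normalization and summarization are not given in the sources used here, and the base was taken as 2. In the deposited log2 table all 34351 probe sets have a median of 0 over the arrays (tolerance 1e-06), so each value is relative to that probe set's own median and no absolute level is known. The medians of the arrays lie between -0.002105 and 0.002304 with similar quartiles, which shows arrays on a common scale. The direction of the scale was read from Xist, which was higher on the arrays labelled female, and from 3 Y-linked genes, which were higher on those labelled male. The number of arrays, not a depth of reading, limits the precision. The median standard error of a difference between the sexes was 0.0497 on the log2 scale.

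Probe sets were named from the platform annotation supplied with the data. Of the probe sets, 23521 had 1 gene symbol, 1814 had several and were left out of gene results, and 9016 were unnamed here. Entrez IDs of 23328 of the named probe sets matched the RefSeq gene table of the assembly GRCm38.p6, and 0 symbols needed an update. That table also gave the chromosome by which genes were called autosomal or sex-linked. The sources used here name no genome build, so no coordinates are given. Probe sets of a gene were averaged, giving 22180 genes, of which 1082 had more than 1 probe set. The plan had been to keep the brightest probe set of a gene and to try filters on brightness. Centred values hold no brightness, so averaging, listed beforehand as an alternative, took its place and those filters were not run.

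Differences were tested as females minus males with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, sex as the only term), with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05. Genes at least 1.5-fold apart past that threshold were also counted. Pcyt2 and the mean per array of each gene list were also tested with exact two-sided permutation tests, which cannot go below 0.0286 with 4 arrays against 4. The 33 gene lists, covering sex-linked genes, lipid and energy metabolism, cardiac muscle, stress and immune responses and markers of the cell types a heart sample can hold, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 33 lists. Camera was repeated with an estimated correlation, and fry was run as a test of each list by itself. Members of the lists were chosen from general knowledge, not from these arrays.

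The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule named Pcyt2, Xist and the Y-linked genes. It then named up to 12 autosomal genes per direction with the largest differences past the threshold, filled to 6 per direction by smallest p where fewer passed, without predicted, microRNA, small nucleolar RNA or olfactory and vomeronasal genes. Of each list it named up to 4 members past the threshold, or else the 2 members with the smallest p. Any other gene named was chosen after its values were seen.

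The code was tested on simulated data for the comparison of females with males, with normal noise at each of the 22180 genes' own spread and 200 changed genes in each of 10 runs. It recovered 51.5% of genes changed by 0.25 on the log2 scale, 89.7% of those changed by 0.5 and 99.5% of those changed by 1. False calls were 4.92% of calls. Many changed genes ease the Benjamini-Hochberg threshold, and the real arrays gave only 7 calls. The recovered shares thus overstate what could be called here: Acta1, with a difference of -1.15, had an adjusted p of 0.137. A list shifted by 0.2 was called in 10 of 10 runs. The simulated genes vary independently, so the test says little about errors of list tests on genes that vary together.

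Alternatives were quantile normalization, median centring of arrays, all probe sets each tested by itself, eBayes with trend and robust settings, array weights, the replicate number as a block, the adipocyte or the atrial list as a covariate, each array left out in turn, other thresholds, and for lists a background without sex chromosomes. Those added after seeing the data were protein-coding genes only, autosomal genes only and a covariate of fast skeletal muscle genes. Also added then were leaving out the 3 arrays with the highest Myh4 or the 2 with the highest Alb, and leaving out Acta1 from the 2 lists that hold it. Each covariate was centred within each sex. It takes up variation between hearts of a sex and leaves the difference between the sexes unchanged, so it does not adjust for unequal tissue content.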

Results

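RNA from the hearts of 8 Pcyt2 heterozygous mice, 4 males and 4 females aged 8 months, was measured on 8 expression arrays, and 22180 genes were compared between the sexes. Pcyt2 encodes the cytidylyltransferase that controls phosphatidylethanolamine synthesis from ethanolamine. Values are log2 values relative to each probe set's median over the 8 arrays, and differences are females minus males. Group values are given as mean ± SD over 4 arrays.

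The targeted gene, Pcyt2, had a log2 value of 0.09 ± 0.20 (SD, n = 4) in males and 0.04 ± 0.14 (SD, n = 4) in females. The difference of -0.05 (95% interval -0.28 to 0.18) was smaller than the SD of either sex. The sexes were not told apart (exact two-sided permutation test, p = 0.743), and the interval leaves a modest difference possible. Over 19 alternatives the difference ran from -0.19 to 0.02, so its direction is not settled. All arrays carry the same genotype, so this comparison does not check the loss of an allele. Of 16 measured genes of ethanolamine and choline phospholipid synthesis, 8 had higher means in females and 8 in males, with a mean difference of 0.01 and a median of -0.01 (camera, adjusted p = 0.885). Its members with the smallest p were the lipid phosphatase gene Plpp1, with a difference of -0.12 ± 0.05 (SE), and the choline transporter gene Slc44a1, with 0.11 ± 0.05 (SE), at adjusted p of 0.683 and 0.701. The list had 0 members past the threshold over all genes and 0 when adjusted over the list alone, with 2 at an unadjusted p under 0.05.

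Sex-linked genes matched the sex label of every array. The 3 measured Y-linked genes were all higher in males. Females lack these genes and males lack active Xist, and the background level of these probe sets is not known here, so the folds of these 4 genes are lower bounds. Eif2s3y, a subunit gene of a translation initiation factor, was at least 8.14-fold higher (log2 difference -3.03 ± 0.12 SE, limma adjusted p = 5.67e-06). Uty, a relative of histone demethylases, was at least 5.53-fold higher (-2.47 ± 0.06 SE, adjusted p = 2.22e-07), and the histone demethylase gene Kdm5d was at least 3.68-fold higher (-1.88 ± 0.04 SE, adjusted p = 1.59e-07). Xist, the noncoding RNA that silences an X chromosome, was at least 28.6-fold higher in females (4.84 ± 0.20 SE, adjusted p = 1.04e-05). Of 9 measured X-linked genes known to escape inactivation, all 9 had higher means in females, 3 passed over all genes and 7 passed when adjusted over the list alone. After Xist these were led by the histone demethylase gene Kdm6a, 1.64-fold higher (0.71 ± 0.06 SE, adjusted p = 0.00709), and the RNA helicase gene Ddx3x, 1.34-fold higher (0.42 ± 0.04 SE, adjusted p = 0.0187). The Ddx3x call ended in 11 of 20 alternatives, among them 6 of the 8 that left out an array (adjusted p from 0.0156 to 0.126 over those 8 and up to 0.371 over all). As lists, the Y-linked genes (camera, adjusted p = 6.81e-24) and the X-linked genes that escape inactivation (adjusted p = 1.42e-18) both differed. Among the other sex-linked calls, that of Xist ended with trend and robust settings (adjusted p = 0.281, range over alternatives 4.34e-09 to 0.281). Those of Kdm5d (0.0729, range 5.83e-08 to 0.0729) and Uty (0.0691, range 5.83e-08 to 0.0691) ended with quantile normalization. Both settings acted on centred values, which hold no brightness, and quantile normalization moved the mean Y-linked difference from -2.46 to -3.25. How far the centring caused these losses is not known. The Kdm6a call ended without male 3 (0.0546) and without the 2 arrays with the highest Alb (0.0608, range 0.0025 to 0.0608).

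Over all 22180 genes, 7 differed between the sexes at an adjusted p under 0.05, 3 higher in females and 4 higher in males, and 1543 had an unadjusted p under 0.05 against 1109 expected by chance. Besides the 6 sex-linked genes above, 1 autosomal gene passed. This was Ano5, a member of the anoctamin family of membrane proteins found in muscle, which was 1.26-fold higher in males (0.17 ± 0.04 against -0.16 ± 0.05, SD, n = 4 each, limma adjusted p = 0.0293). Ano5 was higher in each male heart than in each female heart, but with any of the 8 arrays left out its adjusted p no longer passed (0.0521 to 0.16), and it ran from 0.0153 to 0.441 over all alternatives. Fitted and adjusted over autosomal genes only, 0 genes passed by limma, and the adjusted p of Ano5 was 0.198. In the fit over all genes, 1468 of the 21065 autosomal genes had an unadjusted p under 0.05. Past the threshold 5 genes were at least 1.5-fold apart, 2 higher in females and 3 higher in males, and all were sex-linked. Quantile normalization left 3 genes, 2 higher in females and 1 higher in males, and leaving out male 3 left 4. In 830 genes, or 3.74%, the female and male values did not overlap, against 2.86% by chance.

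The other autosomal genes named by smallest p did not pass the adjustment. Acta1, the skeletal muscle actin gene that fetal and overloaded hearts also express, had the largest difference among them, with 0.60 ± 0.36 in males and -0.55 ± 0.21 in females (SD, n = 4 each), a 2.21-fold difference (log2 difference -1.15 ± 0.17 SE, adjusted p = 0.137). Its 4 male values lay above its 4 female values. Ddah1, whose enzyme breaks down an inhibitor of nitric oxide synthesis, had a difference of -0.27 (adjusted p = 0.137), and the cyclic nucleotide phosphodiesterase gene Pde11a one of -0.47 (adjusted p = 0.16). Oaz2, an antizyme gene of polyamine control, and Ccm2l had differences of -0.23 and -0.20. With higher means in females, the zinc finger gene Zfp712 had a difference of 0.26 (adjusted p = 0.0876) and the monocarboxylate transporter gene Slc16a7 one of 0.48 (adjusted p = 0.109). Ifih1, a cytoplasmic sensor of viral RNA, the ETS repressor gene Erf, Tvp23b and Dennd6a had differences of 0.18, 0.33, 0.32 and 0.20, all at an adjusted p of 0.252.

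**Figure D1:**
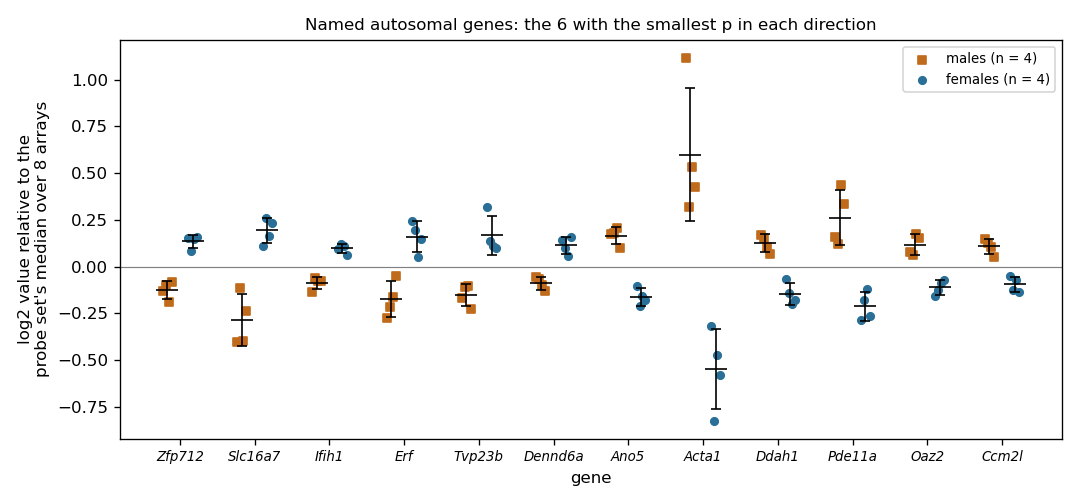
The log2 value of each array relative to the probe set's median (vertical axis) is shown for 12 autosomal genes (horizontal axis), the 6 in each direction with the smallest p after leaving out genes with predicted or clone names, small RNA genes and olfactory or vomeronasal genes, with squares for males, circles for females and black bars for mean ± SD (n = 4). Acta1 shows the widest separation, 0.60 in males against -0.55 in females, and Ano5 alone passed the adjustment over all genes, with an adjusted p of 0.0293.

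Genes of the extracellular matrix and fibrosis had lower values in females. Of 24 measured members, 23 had higher means in males, and the list's mean was 0.11 ± 0.13 in males and -0.10 ± 0.06 in females (SD, n = 4 each; camera, adjusted p = 2.10e-10). The call was lost with an estimated correlation (adjusted p = 0.179), and over all alternatives the adjusted p ran from 4.23e-16 to 0.179. No single member passed over all genes, 0 passed when adjusted over the list alone, and 11 had an unadjusted p under 0.05. The basement membrane collagen gene Col4a2 had a difference of -0.31 ± 0.07 (SE, adjusted p = 0.476), and Lox, whose enzyme crosslinks collagen, one of -0.34 ± 0.09 (SE, adjusted p = 0.499). The exact two-sided permutation test of the list's mean gave p = 0.0571, and male 3 lay among the females at -0.06. Without the 3 arrays with the highest Myh4 the mean difference was -0.09 in place of -0.21.

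The list of hypertrophy and fetal genes also had lower values in females. Of 19 measured members, 16 had higher means in males, and the list's mean was 0.07 ± 0.04 in males and -0.07 ± 0.04 in females (SD, n = 4 each; camera, adjusted p = 5.26e-04). This call held with an estimated correlation (adjusted p = 0.0499) and in all 24 alternatives, including the list without Acta1. The 0.0499 (camera, unadjusted p = 0.00517) was reached only with the sex-linked lists in the same adjustment. Acta1 passed when adjusted over the list alone, and 0 members passed over all genes. Nppb, which encodes B-type natriuretic peptide, had a difference of -0.28 ± 0.09 (SE, adjusted p = 0.592), or -0.10 without the 3 arrays with the highest Myh4. The 3 members with higher means in females were Nppa (0.03), Myh6 (0.02) and Myc (0.06), and Myh7 had a difference of -0.18 ± 0.21 (SE). All 4 male means lay above all 4 female means (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 can give). This full separation rests on Acta1: with it left out, the mean of male 3 falls just below that of female 4.

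Interferon response genes had higher values in females. Of 14 measured members, 12 had higher means in females, and the list's mean was -0.04 ± 0.02 in males and 0.06 ± 0.01 in females (SD, n = 4 each; camera, adjusted p = 5.33e-04). The call held with an estimated correlation (adjusted p = 0.0499) and in all 23 alternatives, and the arrays of the sexes did not overlap (exact two-sided permutation test, p = 0.0286). With an estimated correlation (camera, unadjusted p = 0.00605) this list too passed only with the sex-linked lists in the same adjustment. Ifit1, an interferon-induced RNA-binding protein gene, had a difference of 0.25 ± 0.06 (SE, adjusted p = 0.485), and Usp18, an enzyme gene that removes the modifier ISG15, one of 0.24 ± 0.07 (SE, adjusted p = 0.542). These 2 passed when adjusted over the list alone, and 0 members passed over all genes.

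Adipocyte marker genes had higher values in females. Of 14 measured members, 12 had higher means in females, and the list's mean was -0.11 ± 0.15 in males and 0.17 ± 0.23 in females (SD, n = 4 each; camera, adjusted p = 7.34e-06). The call was lost with an estimated correlation (adjusted p = 0.317, range over alternatives 1.42e-10 to 0.317), 0 members passed over all genes and 0 when adjusted over the list alone. The adipokine gene Retn had a difference of 0.46 ± 0.14 (SE, adjusted p = 0.563) and the carboxylesterase gene Ces1d one of 0.20 ± 0.06 (SE, adjusted p = 0.571). Of the genes of fatty acid and sterol synthesis, Scd1 and Fasn, which encode a desaturase and the fatty acid synthase, had differences of 1.36 ± 0.38 and 0.75 ± 0.22 (SE) at adjusted p of 0.518 and 0.542. Of 18 measured genes of that list, 12 had higher means in females, which did not pass (camera, adjusted p = 0.0929), with 0 members past the threshold adjusted over the list alone.

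Genes of the integrated stress and unfolded protein response had higher values in females, with higher means in 14 of 18 members and a mean difference of 0.07 (camera, adjusted p = 0.00703). The call was lost with an estimated correlation (adjusted p = 0.238, range over alternatives 0.00115 to 0.238) and without male 4 (adjusted p = 0.0799). The endoplasmic reticulum chaperone gene Hsp90b1 had a difference of 0.22 ± 0.05 (SE, adjusted p = 0.38) and passed when adjusted over the list alone, and Calr, a calcium-binding chaperone gene, had one of 0.18 ± 0.06 (SE, adjusted p = 0.563). Genes of fatty acid uptake and oxidation had lower values in females, with higher means in males in 19 of 24 members and a mean difference of -0.06 (camera, adjusted p = 0.0134). This call was lost with an estimated correlation (adjusted p = 0.523, range over alternatives 5.34e-04 to 0.523) and without male 3 (0.072), male 4 (0.128), female 1 (0.0787) or female 3 (0.0643), and without female 1 the mean difference was -0.04. Angptl4, an inhibitor gene of lipoprotein lipase, had a difference of -0.28 ± 0.10 (SE, adjusted p = 0.633), and against the direction of the list Ppargc1a, a coactivator gene of mitochondrial biogenesis, had one of 0.19 ± 0.05 (SE, adjusted p = 0.481). Neither list had a member past the threshold over all genes, and the oxidation list had 0 when adjusted over the list alone.

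The list of markers of skeletal muscle, lung, thymus and lymph node had lower values in females, with higher means in males in 10 of 12 members (camera, adjusted p = 0.01). It was lost with an estimated correlation (adjusted p = 0.445, range over alternatives 1.87e-05 to 0.585), without male 1 (0.093), male 2 (0.0829) or female 4 (0.106), and without Acta1 (0.0893). Acta1 alone passed when adjusted over the list alone, and Myh2, a fast skeletal myosin gene, had a difference of -0.17 ± 0.10 (SE), or -0.07 without male 2. The list's mean was 0.37 in male 1 and 0.42 in male 2, against -0.04 in male 3 and -0.03 in male 4, and between -0.15 and 0.11 in the 4 females. Its mean difference was -0.22, and without male 2 it was -0.14.

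**Figure D2:**
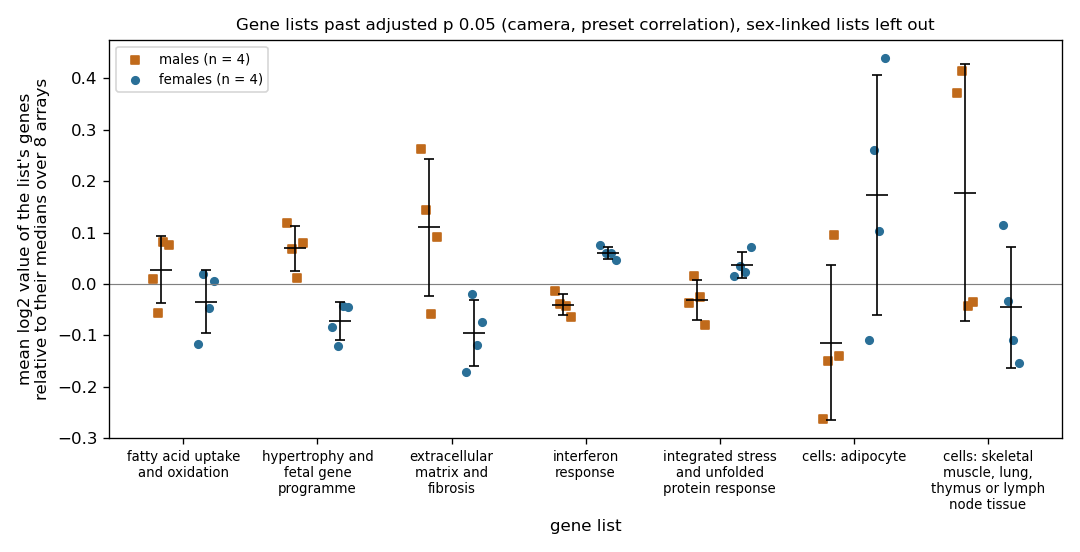
The mean log2 value of a list's genes relative to their medians (vertical axis) is shown per array for the 7 lists other than the sex-linked ones that passed camera at the preset correlation (horizontal axis), with squares for males, circles for females and black bars for mean ± SD (n = 4). The sexes separate fully for the hypertrophy and fetal genes and for the interferon response genes (exact two-sided permutation test, p = 0.0286 each), and overlap for the extracellular matrix and adipocyte lists (p = 0.0571 each). The separation of the hypertrophy list rests on Acta1, without which male 3 falls just below female 4.

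Of the 33 lists, 9 passed camera at the preset correlation, 4 higher in females and 5 higher in males. Of these, 4 held with an estimated correlation: the Y-linked genes, the X-linked genes that escape inactivation, the hypertrophy and fetal genes and the interferon response genes. The hypertrophy and interferon lists held only because the sex-linked lists, which differ by chromosome content, stood in the same adjustment. Among lists of energy metabolism that did not pass, oxidative phosphorylation had 13 of 21 members with higher means in females (camera, adjusted p = 0.601), glucose use and insulin signalling 14 of 25 (0.728) and triglyceride synthesis and lipid droplets 6 of 22 (0.241). The droplet coat genes Plin2 and Plin5 had differences of -0.15 ± 0.05 and -0.25 ± 0.10 (SE), and the glucose and insulin genes Pik3r1 and Pkm had 0.18 and -0.12. Contraction and calcium handling had 6 of 20 members with higher means in females (0.181), led by the calcium-binding gene Casq2 at -0.16 ± 0.04 (SE). Cardiac ion channels and connexins had 13 of 18 (0.0983), with the potassium channel gene Kcna5 at 0.18 ± 0.04 (SE, adjusted p = 0.291) past the threshold when adjusted over the list alone. The other member of that list named by the rule, Kcnd2, had a difference of -0.15 ± 0.06 (SE).

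Of the remaining response lists, cytokines and inflammation had 14 of 20 members with higher means in females (camera, adjusted p = 0.461), and the chemokine gene Ccl5, with 0.57 ± 0.13 (SE, adjusted p = 0.437), passed when adjusted over the list alone. Antioxidant and xenobiotic enzymes had 14 of 19 (0.0695), with Cyp2e1 at 0.67 ± 0.22 (SE). The circadian clock had 11 of 16 (0.17), with Per3 at 0.17 and Arntl at -0.20. The glucocorticoid response had 8 of 15 (0.461), with Klf9 at 0.20 (0.13 without male 4) and Angptl4 at -0.28 (-0.35 to -0.13 over the alternatives). Sex hormone receptors and targets had 7 of 11 (0.17), with the estrogen receptor gene Esr1 at 0.10, and the cell cycle had 11 of 17 (0.784), with Ccnd1 at -0.12 and Pcna at 0.11 (-0.08 and 0.07 without female 1).

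Markers of other cell types did not pass. Endothelial markers had 4 of 11 members with higher means in females (camera, adjusted p = 0.076), with the receptor gene Kdr at -0.19, and smooth muscle and pericyte markers 2 of 12 (0.0929), with Myh11 at -0.19. Fibroblast markers had 6 of 11 (0.728), with a mean difference of -0.07, a median of 0.03 and Dpep1 at -0.34. That mean leans on male 1 and female 1, whose list means were 0.18 and -0.19, with the other arrays between -0.06 and 0.03. Lymphocyte markers had 9 of 12 (0.0695), with Cd3g at 0.22, macrophage and monocyte markers 9 of 14 (0.601), with Ly6c2 at 0.17 (0.09 without male 4 and 0.11 without female 2), and neutrophil and mast cell markers 7 of 10 (0.258), with Tpsb2 at 0.11. Epicardial and mesothelial markers had 6 of 10 (0.784), with Upk3b at 0.26 ± 0.26 (SE, 0.45 without female 1, 0.03 without female 4 and up to 0.68 over the alternatives), Schwann cell and neuron markers 4 of 8 (0.728), with Uchl1 at -0.11, and ventricular cardiomyocyte markers 4 of 11 (0.461), with Fhl2 at -0.10. Against Upk3b and Uchl1, the other members named by the rule were Wt1 at -0.08 (-0.12 to 0.003 over the alternatives) and Kcna1 at 0.09. Of the erythroid markers 1 was measured, Slc4a1, whose difference of -0.06 ± 0.11 (SE, adjusted p of the list 0.728) has no settled direction, with values from -0.15 to 0.15 over the alternatives and 0.06 without female 1. Atrial cardiomyocyte markers had higher means in females in 12 of 12 (0.17), with Kcnj3 at 0.13 (0.20 without female 1), and their list mean ran from -0.72 to 0.19 in males and from -0.82 to 0.42 in females.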

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

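The tests in this part, except the splits for the 3 counts of genes, were chosen only after related values had been seen. The 8 arrays can be split into groups of 4 in 35 ways. The real split gave 7 genes past the threshold, 1 autosomal gene, and 5 genes at least 1.5-fold apart. In each case 1 of the 35 splits, the real one, gave as many, and the highest count of another split was 0. For the counts of 7 and 5 this was fixed in advance. All of the 5, and all of the 7 but Ano5, are sex-linked and differ by chromosome content, and every other split mixes the sexes. These 2 comparisons thus say nothing about genes that are not sex-linked. For the autosomal count a chance split is not excluded, because the adjusted p of Ano5 is lowered by the sex-linked calls, which the other splits lack. By the smallest autosomal p, 6 of the 35 splits were as small as the real one (9.24e-06, smallest of the others 5.34e-06), and adjusted over autosomal genes only the real split and the others all called 0.

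For the lists, the splits show how easily camera at the preset correlation makes calls on these arrays: the other splits called a median of 6 lists and up to 13, against 9 in the real split. For 4 lists, 1 of 35 splits, the real one, gave a p as small. For the Y-linked genes (real p 2.06e-25, smallest of the others 0.00404) and the X-linked genes that escape inactivation (8.59e-20 against 1.47e-05) chromosome content fixed this in advance. For the hypertrophy and fetal genes (7.97e-05 against 0.00077) and the interferon response (9.70e-05 against 0.00739) the real split had the smallest p for each taken alone. This is the most that 35 splits can show, and these lists were split after their means had been seen. The 4 lists were read among 33, of which 5 had means at the smallest exact two-sided permutation p of 0.0286 against 0.943 expected by chance. Adjusted over the 33 that p was 0.189. Among the 5 were the Y-linked and X-linked lists, whose separation chromosome content fixed in advance. They raise the count of 5 and lower the adjusted 0.189. The splits are thus too few to exclude chance for the hypertrophy and interferon lists once all lists are counted. For the others chance is not excluded. The count was 3 of 35 for extracellular matrix and fibrosis (1.91e-11 against 2.79e-17), 3 for the adipocyte list (8.90e-07 against 1.45e-14) and 3 for the stress and unfolded protein response (0.00149 against 4.77e-04). It was 7 for fatty acid uptake and oxidation (0.00365 against 3.21e-08) and 9 for the markers of skeletal muscle, lung, thymus and lymph node (0.00243 against 1.26e-06).

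The matrix genes were higher in males, with a median difference of -0.18. A higher share of fibroblasts in the male samples could give this, but would raise other fibroblast markers too. The 9 fibroblast markers outside the matrix list had a median difference of 0.035 with a bootstrap interval of -0.21 to 0.15, which holds 0 and the matrix value alike and leaves this open, although the gap between the means of these 2 sets of genes differed between the sexes (exact two-sided permutation test, p = 0.0286). Adjoining tissue that carries skeletal muscle may also add matrix RNA, and without the 3 arrays with the highest Myh4 the mean difference was -0.087 (95% interval -0.30 to 0.12), too wide to decide. Sex itself stays open and untested, and chance stays open by the splits above.

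Acta1 had a difference of -1.15 between the sexes. The values argue against skeletal muscle RNA in the male samples as its source, since without the 3 arrays with the highest Myh4 the Acta1 difference was still -1.105 ± 0.11 (SE), although its adjusted p was 0.121. Signal shared with other actin genes would need such a gene to differ by a like amount, and the most negative difference among Actc1, Acta2, Actb and Actg1 was -0.17, in Acta2. A difference between the sexes in cardiac Acta1 is thus a hypothesis these values could carry, found and tested on the same arrays.

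Adipocyte markers were higher in females by 0.29 on average. More fat tissue in the female samples is a candidate explanation. After removing sex, the 14 markers had a mean pairwise correlation across arrays of 0.424, above all of 1000 random lists of the same size, whose 95th percentile was 0.08. Genes under shared control in the heart would vary together as well. The glucocorticoid and cell cycle lists, at 0.431 and 0.301, also lay above that percentile, while the macrophage and interferon lists, at 0.072 and -0.055, did not. Exceeding random lists is thus not particular to fat tissue. Of the 14, Ces1d and Cyp2e1 also stand in the antioxidant list and Cidea and Cidec in the lipid droplet list, and Fabp4, abundant in fat and in capillaries, differed by -0.01. Female 4 had the highest list mean, 0.44, and without it the difference was 0.20, between the full difference and none. Sex stays open and untested.

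Of 216 groups of 4 values examined, 10 held an array far from the other 3, against 10.8 expected by chance. These were Xist in male 4 (-1.995, others -3.02 to -2.89), Zfp712 in female 2 (0.085), Tvp23b in female 1 (0.32), Angptl4 in male 1 (0.34), Ifit1 in female 1 (0.26), Hsp90b1 in male 2 (-0.042), Kdr in female 2 (0.0902), Myh11 in female 1 (-0.10), Cd3g in female 1 (0.24) and the mean of the neutrophil and mast cell list in female 4 (0.038). Outside the named genes, 3 probe sets without a gene name here passed an adjusted p of 0.05 when all probe sets were tested, 2 higher in females by 3.72 and 4.99 and 1 higher in males with a difference of -2.83.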

How the results depend on the processing

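The alternatives with the 3 arrays of highest Myh4 or the 2 of highest Alb left out, the fast skeletal muscle covariate, protein-coding genes only, autosomal genes only and Acta1 left out were chosen after seeing the data. Filters on brightness and the brightest probe set could not be run on centred values. Centring also hides signal over background, so genes near background cannot be told from others. Quantile normalization and the eBayes trend acted on the centred values, so how far the centring caused the calls lost under them is not known. Unless stated, the cause of a change was not tested.

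The count of genes differing (7) was 3 under quantile normalization, 4 to 7 with an array left out and 1543 at an unadjusted p under 0.05. The autosomal count (1) was 0 under quantile normalization, 0 with the adipocyte covariate, 2 with the atrial covariate, 0 without the 3 arrays of highest Myh4, 0 adjusted over autosomal genes only, 0 to 1 with an array left out, 2 at an adjusted p under 0.1 and 1468 at an unadjusted p under 0.05. The count at least 1.5-fold apart (5) was 3 under quantile normalization, 8 with all probe sets, which adds the unnamed ones, and 14 at an unadjusted p under 0.05. The replicate number as a block gave 8 genes, 1 autosomal and 5 at least 1.5-fold apart. Of these 8, 5 were called without the block, and the autosomal gene was Acta1 (adjusted p = 0.0181) in place of Ano5 (0.208). Deviations of arrays with the same number correlated at 0.137, 0.097, 0.0062 and 0.091, and 2 of 4 males correlated best with the female of their number. These values are too few to settle whether the numbers pair the hearts. The model without the block was the one planned. Pcyt2 had differences of -0.19 to 0.02 over 19 alternatives, with none past the threshold.

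Of the lists, the Y-linked, X-linked, hypertrophy and interferon lists kept direction and call in all alternatives. The covariates were centred within each sex and left every mean difference unchanged, so this is no adjustment for unequal tissue content. With an estimated correlation, the hypertrophy and interferon calls depended on the sex-linked lists in the same adjustment. Adjusted p for other lists follow. With an estimated correlation, fry directional and fry mixed: matrix 0.179, 0.159 and 0.0691, adipocyte 0.317, 0.298 and 0.191, fatty acid oxidation 0.523, 0.493 and 0.191, skeletal muscle, lung, thymus and lymph node 0.445, 0.345 and 0.0608. For the stress response an estimated correlation gave 0.238 and fry directional 0.184, and for antioxidant enzymes fry mixed gave 0.00491. With the adipocyte covariate, fatty acid synthesis was 0.0353, antioxidant enzymes 0.0412 and lymphocytes 0.0353. With the atrial covariate, antioxidant enzymes were 0.0406 and atrial markers 1.31e-04, and with the replicate block atrial markers were 0.00887. A list tested with its own mean as covariate loses spread by design. The atrial 1.31e-04 and the adipocyte list's 1.42e-10 under its own covariate thus add no support. Without Acta1 the skeletal muscle, lung, thymus and lymph node list was 0.0893.

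Without the 3 arrays of highest Myh4, that list was 0.585, the glucocorticoid response 0.0398, smooth muscle 0.0113, macrophages 0.0219 and atrial markers 2.31e-05, and fibroblast markers turned to higher in females at 0.0434. Without the 2 arrays of highest Alb, fatty acid synthesis was 5.87e-04, contraction 0.00866, cytokines 0.00412, the glucocorticoid response 2.36e-05, antioxidant enzymes 0.0078, macrophages 0.0359, lymphocytes 0.0437, epicardial markers 0.0149 and atrial markers 0.00444. With an array left out, the adjusted p ran from 0.00109 to 0.311 for fatty acid synthesis, 7.93e-04 to 0.128 for fatty acid oxidation, 0.00442 to 0.342 for ion channels, 0.00115 to 0.0799 for the stress response, 0.0104 to 0.211 for antioxidant enzymes, 0.0189 to 0.575 for endothelial markers, 0.00522 to 0.27 for smooth muscle, 0.0331 to 0.36 for lymphocytes, 3.09e-05 to 0.945 for atrial markers and 8.12e-04 to 0.106 for skeletal muscle, lung, thymus and lymph node.

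Among named genes other than Pcyt2, 15 of the values with an array left out lost their call and 1 gained it, and 16 of those under other alternatives lost it and 3 gained it, with no called difference changing sign.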

Other observations

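The genes and tests in this part were chosen after their values were seen. Hearts of the same sex differed widely in atrial genes. Bmp10, a growth factor gene of atrial muscle, was at -3.35, 0.39, -2.25 and 0.53 in males 1 to 4 and at -3.46, 0.91, -0.39 and 0.50 in females 1 to 4. The atrial light chain gene Myl7 (-0.42, 0.16, -0.95 and 0.12 in males, -1.04, 0.67, -0.12 and 0.40 in females) and Sln, a regulator gene of the calcium pump (-0.15, 0.39, -0.95 and 0.07 in males, -1.02, 0.74, -0.07 and 0.50 in females) were lowest in male 3 and female 1, and Bmp10 was also low in male 1. The ventricular gene Myl2 stayed between -0.06 and 0.04 on all 8 arrays. Fast skeletal muscle genes stood out in other hearts: Myh4 was 1.57 in male 1, 2.23 in male 2 and 1.03 in female 1, and at most 0.23 elsewhere, and Atp2a1 was 0.97, 1.36 and 0.71 in those 3.

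A few genes stood out in females 1 and 2. The albumin gene Alb was 1.76 and 2.69 there against -0.18 to 0.03 in the other 6 hearts, Mup20 was 1.02 and 0.77, and Apoa2 was 0.41 and 0.37, whereas Apoa1 was -0.03 and 0.41 and Fgb 0.08 and 0.30. The small nucleolar RNA genes Snord104 (1.19 and 1.53) and Snora73b (0.79 and 1.03) were highest in the same hearts. Cyp2b10, a xenobiotic enzyme gene, was 2.06 in female 3 and at most 0.14 elsewhere. The lipogenic genes Scd1 and Fasn were 1.26, 1.38 and 2.11 and 0.63, 0.71 and 1.26 in females 2, 3 and 4, but -0.04 and 0.00383 in female 1, against at most 0.04 and -0.00383 in the males. Over all genes the first principal component, with 23% of the variance, put all males on the opposite side from all females (exact two-sided permutation test, p = 0.0286), and over autosomal genes, with 20.2%, it did not separate them fully (p = 0.171). The component over all genes includes the sex-linked genes, whose large differences favour such a separation.

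Among autosomal genes outside the naming rule, the complement gene C7 had 0.76 ± 0.49 in males and -0.37 ± 0.19 in females, and Ace, whose enzyme makes angiotensin II, had 0.30 ± 0.20 and -0.27 ± 0.15 (SD, n = 4 each). Corin, whose protease activates natriuretic peptides, had -0.18 ± 0.12 in males and 0.15 ± 0.07 in females. All 3 had an adjusted p of 0.267 by limma and male and female values that did not overlap. The X-linked gene Vamp7 had a difference of 0.56 ± 0.07 (SE, adjusted p = 0.0574).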
